A study of Mus musculus with 4 samples.

How the data were processed

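RNA from 4 cultures of mouse shoulder capsule fibroblasts was sequenced, 1 library per group: wild type, miR-26a knockout, knockout with a negative-control siRNA, and knockout with a miR-26a mimic. The labels give 10 nM and 24 h for the negative control and for the mimic. Groups were taken from the sample labels. The submitters' processing notes name FastQC, HISAT, Bowtie2 and the mouse builds GRCm38.p6 and mm10, without versions or roles. The quantification tool, the gene annotation and whether counting used strand are not given in the sources used here.

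The gene table holds 16416 genes with Entrez identifiers. Its read counts, per the file headers, are estimated counts that the authors did not scale by library size, and between 4.99% and 5.28% of them per library have decimals. The authors deposited TPM, which have the same sum in each library up to rounding, and FPKM, which are a constant multiple of TPM within a library. A further set of normalized counts deposited by the authors is a signal equal to the estimated count rounded up and divided by 1 size factor per library, and it was not used for tests. A second table deposited by the authors holds log2 ratios, p-values and false discovery rates of PoissonDis, per the file headers, for 4 pairs of libraries. Spreadsheet dates stood in place of 26 gene symbols, which were restored through the Entrez identifier. Of all identifiers 16369 were found in the RefSeq gene table used for names, and 16283 are protein-coding.

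Counts were scaled with edgeR TMM factors of 0.978, 1.00, 1.02 and 0.997 for wild type, knockout, negative control and mimic. A log2 ratio was computed after adding a prior of 1 count, adjusted to library size. A gene was measured in a comparison with at least 1 CPM in either library, and it was said to differ with a ratio of at least 2-fold and an exact conditional binomial (Clopper-Pearson) interval at 95% that excludes 0. Estimated counts were rounded to whole numbers for the intervals. Intervals cover counting error only, since reads are not independent molecules and no group had a replicate, and the same holds for the floor of 3 counts, which is 0.168, 0.170, 0.151 and 0.162 CPM in the 4 libraries. With 18198033, 17598763, 19392655 and 18584404 counts, depth differed little between libraries, and precision is set by each gene's own count. Fn1, the most counted gene, took 3.08% of counts in the wild-type library and 1.67%, 1.65% and 1.90% in the others.

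Before the data were examined, the comparisons, the rule for differing genes, 34 gene lists, the seed sites, the processing alternatives and the rule for named genes were fixed. A further 4 lists were added after the data were seen. For lists with at least 3 measured genes the median log2 ratio was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Genes were named when among the 10 largest ratios in each direction of a comparison with at least 5 TPM in the higher library, leaving out predicted and clone names, or among the 4 largest absolute ratios of a described list, or as host genes, published targets of miR-26a, genes with opposite ratios in the genotype and mimic comparisons, or the 5 most abundant macrophage markers. Genes with near-identical copies, and overlapping genes on opposite strands, can share reads and are uncertain.

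The 3' UTRs came from the GENCODE M21 annotation of GRCm38 and were found for 15791 genes, 96.2% of the table. Sites were the complement of bases 2 to 8 of the mimic's guide strand, the same followed by A, and the corresponding site of the passenger strand, with both strands as the labels give them. All 7-base sequences present in at least 50 measured genes were scanned by the difference in mean log2 ratio, limited to between -2 and 2, divided by its standard error under equal spread (z). Random lists for sites were also matched on 3' UTR length in 10 bins.

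The procedure was tested on simulated Poisson counts. In the simulated knockout to wild-type comparison 98% of genes changed 2.5-fold and 2% of genes changed 1.5-fold were called, with 25 unchanged genes of 12578 simulated called. In that of mimic and negative control the shares were 100% and 0%, with 15 unchanged genes of 12381 called, and in that of negative control and untransfected cells 98% and 2%, with 18 of 12398. Intervals held the true ratio for 95.3%, 95.7% and 95.5% of genes, in the same order. For mimic and negative control, of 100 simulated lists of 700 genes without a shift, out of 15791 genes with a 3' UTR, 7 lay outside the middle 95%. A 7-base sequence in 363 genes, shifted by -0.2, was the lowest in 20 of 20 simulations. Overlaps of comparisons that share a library were set against 20 simulations without an effect of the oligonucleotides, which hold counting error only. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were DESeq2 size factors, total counts, deposited TPM with log2(value + 1), a prior of 5 counts, no filter, a filter at 5 CPM, a 4-fold limit, no interval criterion, the untransfected library as the reference of the mimic, and other site definitions.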

Results

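Fibroblasts of the shoulder joint capsule were profiled by RNA sequencing to search for the target genes of the microRNA miR-26a, whose loss was studied in mice with an immobilized shoulder, a model of frozen shoulder. MicroRNAs are short RNAs that pair through their 5' end, the seed, with sites in the 3' untranslated region (3' UTR) of transcripts and usually lower those transcripts. The cells had grown out of capsule tissue taken 1 week after immobilization and were used at passage 2. There were 4 libraries, 1 per group, from wild-type cells, from miR-26a knockout cells, and from knockout cells transfected for 24 h either with a negative-control siRNA or with a double-stranded miR-26a mimic. Estimated counts summed to 18198033 in the wild-type, 17598763 in the knockout, 19392655 in the negative-control and 18584404 in the mimic library. Counts above 0 were present for 15370, 15150, 15201 and 15202 of 16416 genes, in the same order. With a single library per group no difference has a replicate check, so no p-value is given. Each log2 ratio is printed with its exact 95% binomial counting interval in parentheses, which covers counting error only, and every direction below compares libraries, not conditions.

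MiR-26a itself was not measured here, so the knockout labels were not checked against the targeted gene. The microRNA is encoded within introns of Ctdspl (Entrez Gene 69274) and Ctdsp2 (52468), phosphatase genes whose host transcripts were counted. Ctdspl was at 12.59 TPM in the wild-type and 11.79 TPM in the knockout library, a log2 ratio of 0.01 (-0.18 to 0.20). Ctdsp2 was lower in the knockout library, at 98.18 against 184.55 TPM, a log2 ratio of -0.77 (-0.82 to -0.71). It stood at 102.1 TPM with the negative control and 83.34 TPM with the mimic, and its 3' UTR holds a miR-26a site at 126997566 to 126997572 of chromosome 10 (GRCm38). Ctdsp1, a related gene, had a log2 ratio of -0.21 (-0.30 to -0.11) between knockout and wild type.

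The first comparison asked how the cells of knockout mice differ from those of wild-type mice. Genes of cell division and macrophage genes were higher in the knockout library, and genes of the extracellular matrix were lower. All 32 measured genes of the G2/M list, which act in mitosis, were at least 2-fold higher, with a median log2 ratio of 1.36. Among them Cdca3 reached 1.62 (1.38 to 1.89) and Top2a, the DNA topoisomerase of dividing cells, 1.58 (1.47 to 1.69). Of 32 S phase genes 17 were at least 2-fold higher and none lower, with a median of 1.02 and with Rrm2, a subunit of ribonucleotide reductase, at 1.53 (1.34 to 1.72). Macrophage markers were 2-fold higher for 11 of 19 measured genes and above 0 for all 19, with a median of 1.06. Cd14, a receptor for bacterial lipopolysaccharide, had 165.34 TPM in the knockout and 36.43 TPM in the wild-type library, and Csf1r, the receptor for macrophage colony-stimulating factor, had 408.39 and 140.65 TPM. The medians of these 3 lists lay above all or nearly all of 10000 random lists matched on expression, at percentile 100.

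Macrophage transcripts were abundant in every library, although the cells were named fibroblasts in the labels. Lyz2, which encodes lysozyme, had 14912.62 TPM in the wild-type and 18990.65 TPM in the knockout library, with 17285.61 TPM after the negative control and 17807.07 TPM after the mimic. C1qc, C1qb and C1qa, the subunits of complement C1q, had 1395.08, 1438.48 and 899.26 TPM in the wild-type library and 2466.34, 2554.59 and 1694.72 TPM in the knockout library. Tyrobp, a signalling adaptor of myeloid cells, had 1049.64 and 2072.06 TPM.

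Collagen genes were lower in the knockout library, where macrophage markers were higher. Of the 21 collagens in the list, all measured, 10 were at least 2-fold lower and none higher. Their median log2 ratio was -0.94 at percentile 0.0. Col2a1, a collagen outside this list, was at least 2-fold higher in the knockout library. Col3a1 had 1265.33 against 4127.74 TPM, a log2 ratio of -1.58 (-1.59 to -1.56), and Col5a3, Col14a1 and Col8a2 had ratios of -1.72 (-1.79 to -1.64), -1.46 (-1.60 to -1.32) and -3.34 (-3.86 to -2.92). Matrix glycoproteins and crosslinking enzymes were lower for 9 of 36 genes and higher for 1, with a median of -0.67 at percentile 0.0. Eln, which encodes elastin, had 38.74 against 328.04 TPM, a log2 ratio of -2.96 (-3.04 to -2.88), and Mfap4, an elastic fibre protein, had a ratio of -4.25 (-5.19 to -3.59). Matrix proteases and their inhibitors went both ways, with 7 of 28 genes lower, 3 higher and a median of -0.51 at percentile 0.0. The collagenase Mmp13 had a ratio of -3.70 (-3.87 to -3.55) and the gelatinases Mmp9 and Mmp2 of -3.90 (-4.48 to -3.45) and -1.84 (-1.88 to -1.80), whereas the inhibitor Timp3 was higher, at 1.83 (1.80 to 1.85). General fibroblast markers were lower for 6 of 17 genes, with a median of -0.58 at percentile 0.0. Among them Dpt had a ratio of -2.60 (-2.75 to -2.46) and Fap, a fibroblast surface protease, of -2.07 (-2.29 to -1.87).

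Contractile genes of myofibroblasts did not follow the collagens. Of 18 measured members 5 were at least 2-fold higher in the knockout library and 2 lower, with a median of 0.28 at percentile 98.7. The smooth muscle genes Actg2, Cnn1 and Tpm2 had log2 ratios of 3.16 (2.95 to 3.38), 2.05 (1.79 to 2.33) and 1.52 (1.42 to 1.62), and the collagen receptor subunit Itga11 had -1.49 (-1.52 to -1.45). Genes of the TGF-beta response had a median of 0.04 at percentile 55.9, with 3 of 26 higher, 1 lower, and Id1 at 2.96 (2.63 to 3.33). Interferon-stimulated genes were higher for 14 of 38 members and lower for none, with a median of 0.75 at percentile 100, in the library with the higher macrophage markers. Ccl5, a chemokine, had a log2 ratio of 2.93 (2.02 to 4.35) and Oas3, an antiviral synthetase, of 2.32 (1.64 to 3.20). Cytokines and chemokines went both ways, with 6 of 28 higher and 5 lower and a median of 0.17 at percentile 95.2. Saa3, an acute-phase protein, stood at 3.90 (3.34 to 4.65) and Cxcl12, a chemokine of stromal cells, at -2.84 (-2.88 to -2.79).

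Markers of fat, muscle and nerve sheath were lower in the knockout library. Adipocyte markers were lower for 6 of 9 genes with a median of -1.86 at percentile 0.0, and Adipoq, the adipokine adiponectin, was counted 204 times in the wild-type and 1 time in the knockout library, a ratio of -6.70 (-12.97 to -5.17). Skeletal muscle markers were lower for 7 of 10 genes, with a median of -1.91 at percentile 0.01, and markers of Schwann cells were lower for 5 of 9, with a median of -1.15 at percentile 0.0 and Sox10, a transcription factor of glia, at -1.40 (-1.60 to -1.22). Markers of pericytes and smooth muscle had a median of -0.68 at percentile 0.16. Synovial lining markers had a median of -0.46 at percentile 1.14, with 2 of 9 at least 2-fold lower and 1 higher. Markers of endothelial cells, of cartilage and tendon, and of osteoblasts lay within the middle 95% of random lists, with medians of 0.04, -0.22 and -0.47 at percentiles 66.4, 28 and 12. The 1 measured epithelial marker, Krt19, was higher, at 3.86 (2.46 to 7.50).

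In all, 756 genes were at least 2-fold higher and 896 at least 2-fold lower in the knockout library, 12.9% of 12803 measured genes. The largest higher ratios were those of Parvg, a focal adhesion protein of blood cells, at 5.03 (4.34 to 6.05), Mfng at 4.45 (3.35 to 6.65), Ankrd1 at 3.95 (3.32 to 4.82) and the chemokine receptor Ccr1 at 3.92 (3.46 to 4.48). Mest, an imprinted gene, was the lowest, with 1.32 against 197.7 TPM and a ratio of -7.07 (-7.69 to -6.59). Ptn, a heparin-binding growth factor, Wnt16 and the BMP antagonist Chrdl1 had ratios of -5.09 (-5.85 to -4.53), -4.75 (-5.77 to -4.05) and -4.49 (-5.78 to -3.68). Ibsp, which encodes bone sialoprotein, had 96 counts in the wild-type and 0 in the knockout library, so that it was at least 31.8-fold lower against a floor of 3 counts. Counts were 1 in the knockout library for Egfl6, Cfd and Car3. On deposited TPM values 433 genes were at least 2-fold higher and 683 lower, and at 5 CPM or more the counts were 556 and 556.

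**Figure D1:**
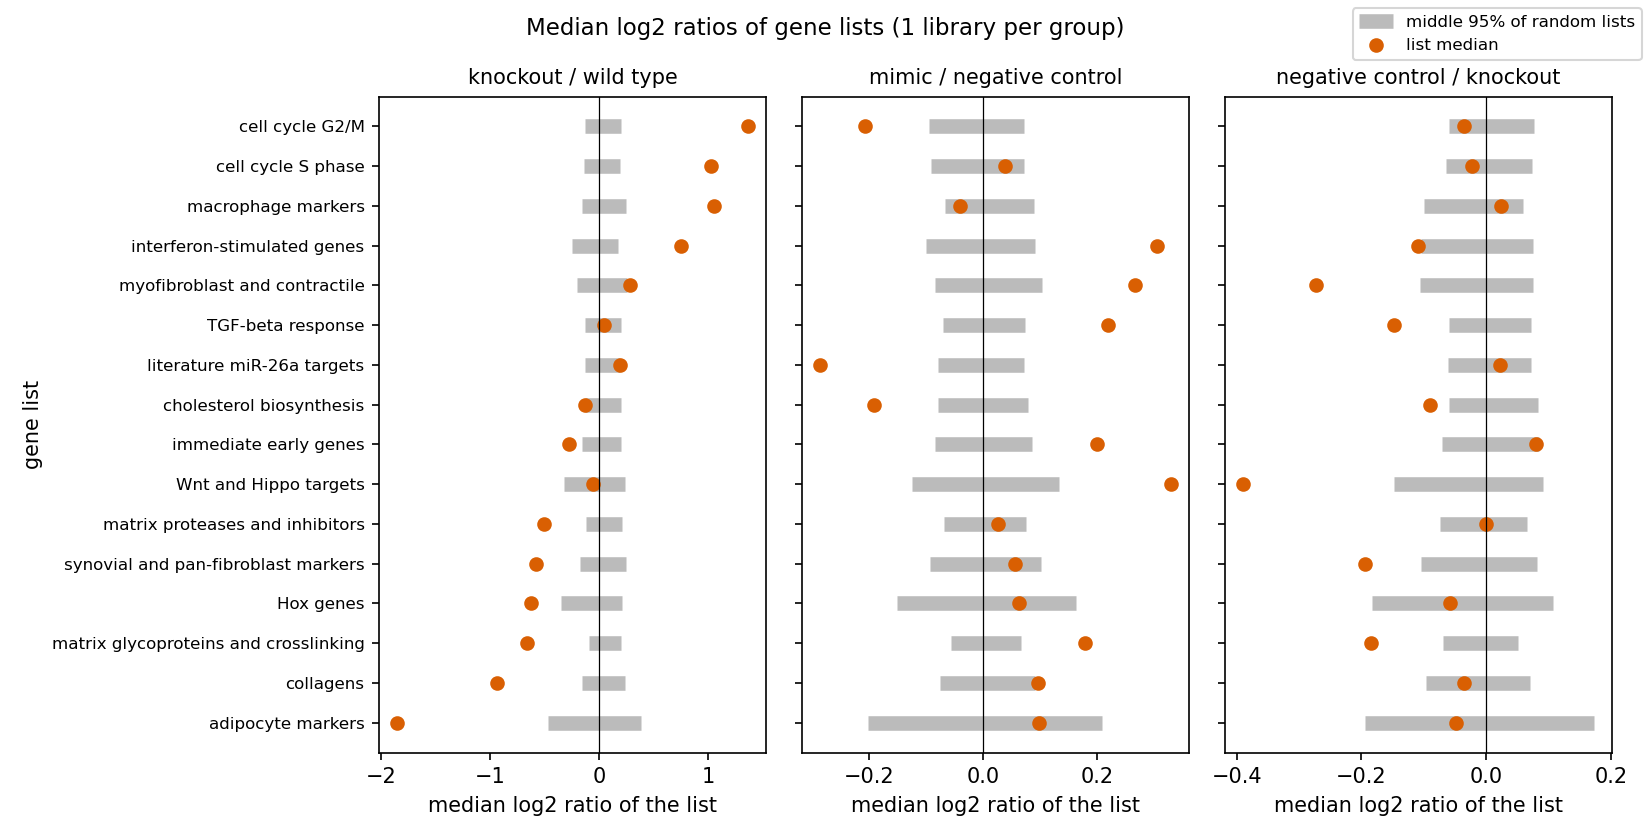
Median log2 ratio (x axis) of 16 gene lists in the 3 comparisons, 1 library per group; points are list medians, and grey bars hold the middle 95% of 10000 random lists matched on expression. In the knockout against the wild-type library the G2/M list lies at 1.36 and the collagens at -0.94, on an axis several times wider than those of the transfection comparisons.

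**Figure D2:**
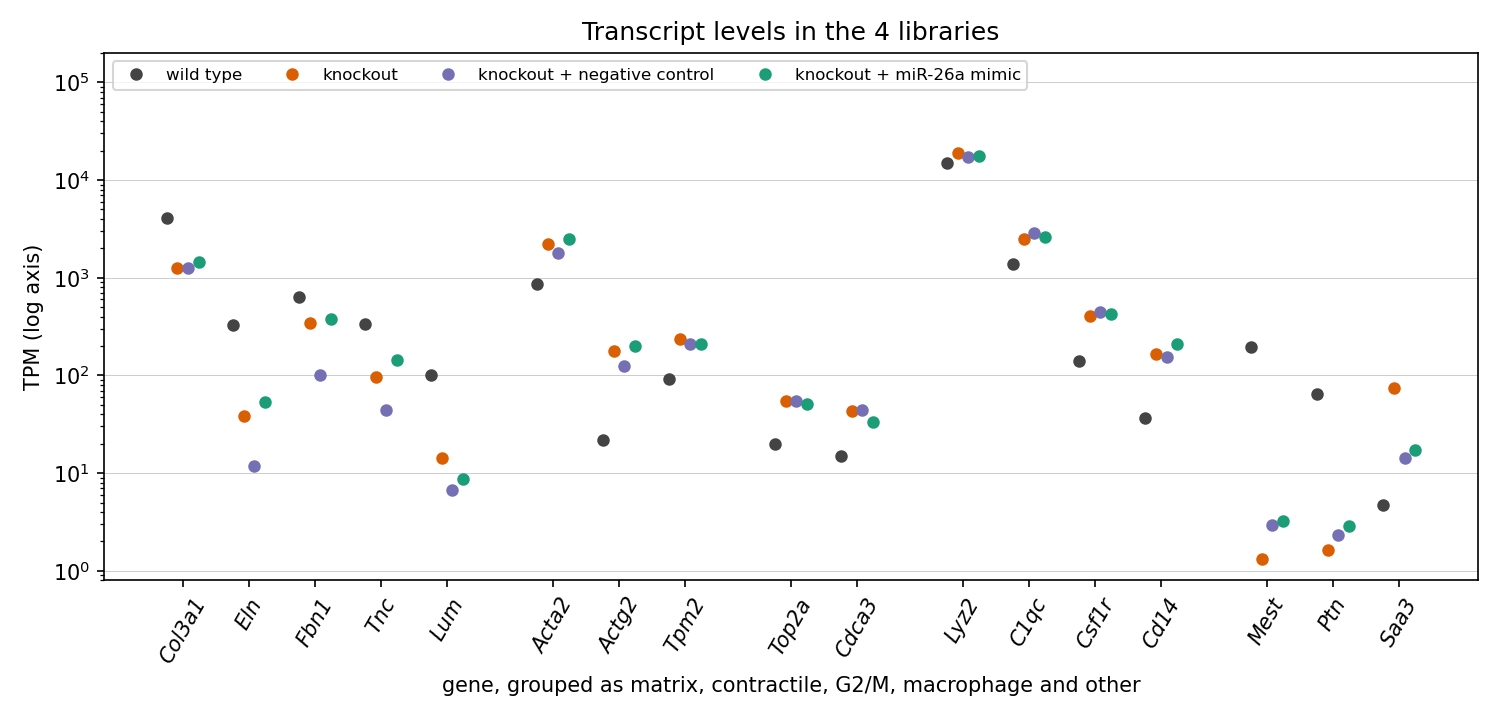
Transcript levels in TPM (log axis) of 17 genes in the 4 libraries, 1 point per library, with no error bars because each group is a single library. Col3a1 lies at 4127.74 TPM in the wild-type library and 1265.33 TPM in the knockout library, and Fbn1 lies lowest with the negative control, at 101.48 TPM.

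The mimic comparison asked which genes respond when miR-26a is given back to knockout cells, with the negative control as reference. Published miR-26a targets were lower in the mimic library as a list, with a median log2 ratio of -0.29 at percentile 0.0. Of the 30 measured members 21 were below 0 and 9 above, and none reached 2-fold. Slc7a11, a cystine transporter, had a ratio of -0.97 (-1.18 to -0.78), Plod2, a collagen lysyl hydroxylase, of -0.84 (-0.91 to -0.77), Acsl3, a fatty acid activating enzyme, of -0.68 (-0.82 to -0.54) and the cytokine Il6 of -0.64 (-1.08 to -0.23). A miR-26a site was found in the 3' UTRs of Slc7a11, Plod2 and Acsl3 but not for Il6. Against the untransfected knockout library the list's median was -0.13 at percentile 0.08 and Plod2 stood at -0.83 (-0.90 to -0.76). With that reference 21 of 31 measured members were below 0 and 10 above, and 1, Tet1, was at least 2-fold lower. G2/M genes were below 0 for 31 of 32 members with either reference, with medians of -0.21 against the negative control and -0.26 against the untransfected cells, both at percentile 0.0. Genes of cholesterol synthesis had medians of -0.19 and -0.32, both at percentile 0.0. None of the G2/M and cholesterol genes reached 2-fold against the negative control.

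Interferon-stimulated genes were higher in the mimic library with both references, at a median of 0.30 against the negative control and 0.18 against the untransfected cells, each at percentile 100. Usp18, Ifi44 and Ifit1, all induced by interferon, had ratios of 1.42 (0.71 to 2.26), 1.09 (0.51 to 1.76) and 1.08 (0.72 to 1.46) to the negative control. Immediate early genes had medians of 0.20 at percentile 100 and 0.28 at percentile 100. Matrix glycoproteins were higher for 3 of 36 genes against the negative control, with a median of 0.18 at percentile 100, but had a median of 0.03 at percentile 77.8 against the untransfected cells. Collagens of the list went both ways, with 2 of 21 at least 2-fold higher against the negative control and 0 against the untransfected cells. In the same order 8 and 7 were below 0, with medians of 0.10 at percentile 98 and 0.18 at percentile 100. The contractile, the Wnt and Hippo, and the TGF-beta response lists had medians of 0.27, 0.33 and 0.22 against the negative control. Against the untransfected cells these 3 lists stood at 0.03, -0.03 and 0.05, in the same order. Macrophage markers had a median of -0.04 at percentile 11.4 and none of 20 reached 2-fold.

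At least 2-fold higher were 107 of 12512 measured genes, and 44 were at least 2-fold lower, with 43 and 10 at 5 CPM or more. After Zfp966, the largest ratios among genes with at least 5 TPM were those of Npnt, Eln, Fbn1 and Tnc, which encode matrix proteins. Eln stood at 2.14 (1.99 to 2.30), Fbn1, the microfibril protein fibrillin-1, at 1.90 (1.87 to 1.94) and Tnc, tenascin-C, at 1.67 (1.61 to 1.73). Npnt stood at 2.19 (1.89 to 2.53). The exocyst subunit Exoc4 stood at 1.56 (1.47 to 1.65), and Cemip, a hyaluronan-binding protein, was also among the largest. Among the lower genes were the transporter Slc22a23 at -1.19 (-1.46 to -0.93), the homeobox gene Hoxa9 at -1.15 (-1.45 to -0.86), the metalloprotease Adam19 at -1.10 (-1.18 to -1.02) and the Wnt inhibitor Apcdd1 at -1.08 (-1.39 to -0.79). These 4 genes hold a miR-26a site in the 3' UTR, in Adam19 at 46147251 to 46147257 of chromosome 11 and in Hoxa9 at 52223796 to 52223802 of chromosome 6 (GRCm38), whereas Lyzl4, Fam131b, H1f10 and Perp, also among the largest lower ratios, hold none. Against untransfected cells the mimic ratios were -0.965 (-1.24 to -0.70) for Slc22a23, -0.82 (-1.14 to -0.52) for Hoxa9 and -0.80 (-1.12 to -0.49) for Apcdd1. That of Adam19 was only -0.27 (-0.37 to -0.17), and Adam19 was higher in the negative-control library than in untransfected cells, at 0.83 (0.75 to 0.91). Zfp966, at 2.31 (1.88 to 2.78), and Rpl37rt, at -1.25 (-2.50 to -0.31), belong to families of near-identical copies, and their ratios are uncertain. With the untransfected library as reference the counts were 33 higher and 59 lower, of which 9 and 13 were also among the 107 and 44.

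Genes with a miR-26a site, the 7 bases TACTTGA that pair with bases 2 to 8 of the microRNA, were lower in the mimic library. The median log2 ratio to the negative control was -0.04 for the 1518 measured genes with a site and -0.00 for the others, at percentile 0.0 of random lists matched on expression or on expression and 3' UTR length. The 657 genes with the 8-base site TACTTGAA had a median of -0.08, and 65.1% of them lay below 0, against 50.8% of genes without it. Genes with only the 7-base site had a median of -0.02, at percentile 14.1 when matched on expression and 0.0 when also matched on length. Against the untransfected knockout library the genes with a site had a median of -0.04 and the others 0.01, again at percentile 0.0. Among 16187 7-base sequences TACTTGA had the lowest z in the mimic to negative-control ratios, at -9.13, followed by the overlapping ACTTGAA at -7.35, and it was also the lowest of 16193 against the untransfected cells, at -7.79. Sites for the passenger strand of the mimic went with a median of 0.01, at percentile 99.9 when matched on expression and 5.42 when also matched on length. Against untransfected cells their median was 0.02, at percentiles 99.7 and 0.27 in the same order. Of the genes at least 2-fold lower with the mimic than with the negative control, 6 of 35 with an annotated 3' UTR held a miR-26a site, 17.1% against 12.3% of all measured genes, and against untransfected cells 5 of 53 did, 9.43%. At 1.4-fold, a limit chosen after the values were seen, 101 of 368 genes held a site, 27.4%, and 83 of 430 against untransfected cells, 19.3%.

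Between the knockout and the wild-type library the place of the same genes depended on the random lists they were set against. The 1549 genes with a site had a median log2 ratio of -0.03 and the others 0.02, and with plain total-count scaling the median of the former was 0.01. It lay at percentile 0.01 of random lists matched on expression and at percentile 95.4 of lists also matched on 3' UTR length. The genes with 8-base sites lay at percentiles 3.39 and 94.4, in the same order, and the set that also takes in ACTTGAA, with a median of -0.01, at 0.14 and 100. Genes with sites for the passenger strand, with a median of -0.035, lay at 0.0 and 93.8. The change of place with length matching was therefore not particular to miR-26a sites. TACTTGA ranked 38 from the highest among 420 rearrangements of its bases in this comparison. Published targets had a median of 0.18 at percentile 97.3, within the middle 95% of random lists, with 19 of 31 above 0 and 12 below. Ptgs2, a prostaglandin synthase, stood at 1.22 (0.99 to 1.46), Ccne2, cyclin E2, at 1.14 (0.85 to 1.44) and Tet1, a DNA demethylation enzyme, at -1.49 (-2.30 to -0.81).

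**Figure D3:**
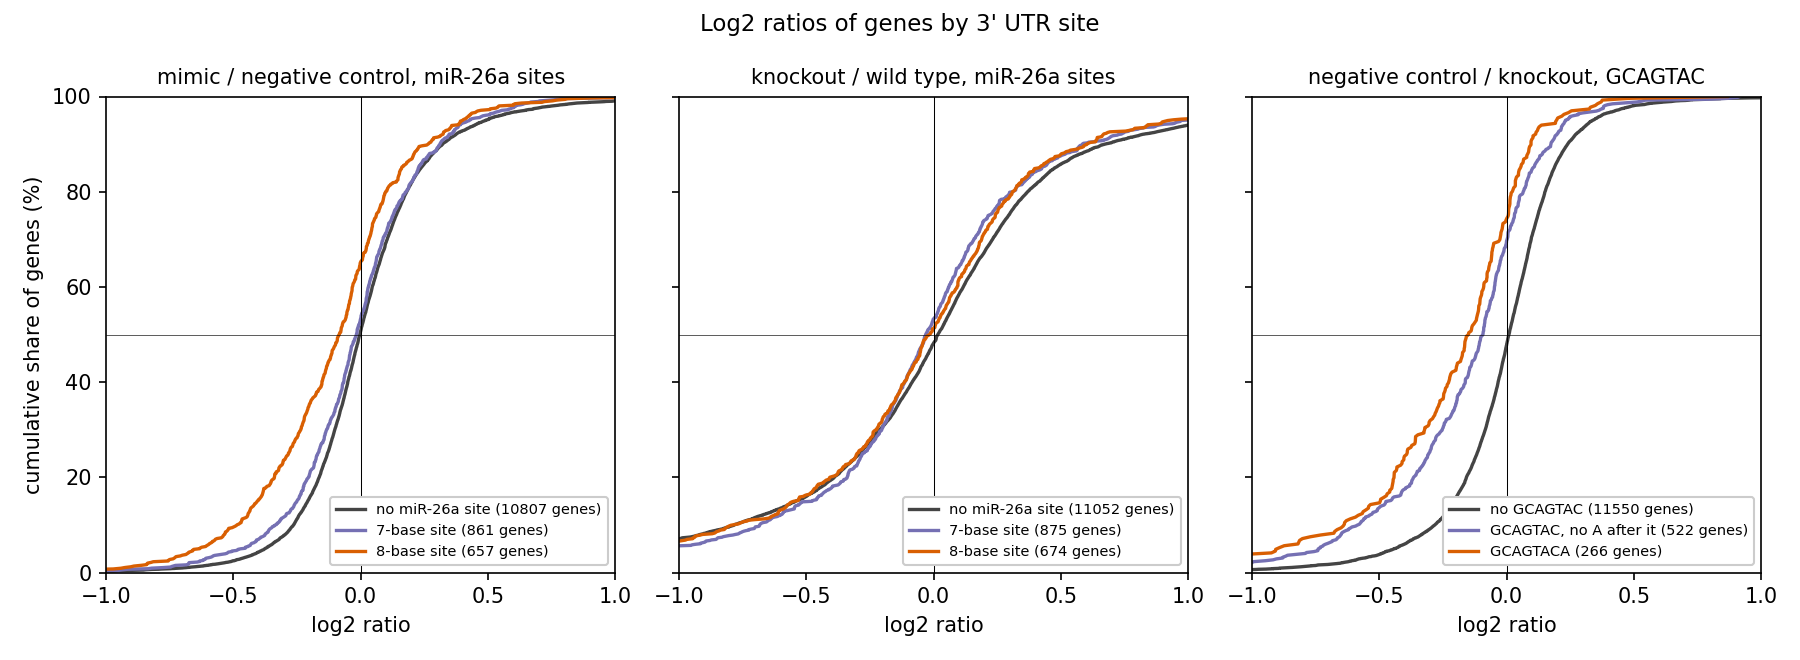
Cumulative share of measured genes (y axis, %) by log2 ratio (x axis, shown from -1 to 1), split by the site in the 3' UTR, for the mimic against the negative control, the knockout against the wild type, and the negative control against the untransfected knockout. The curve of 8-base miR-26a sites lies left of the others with the mimic (median -0.08), and that of GCAGTACA lies furthest left with the negative control (median -0.15).

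The negative control was compared with untransfected knockout cells to measure what transfection with that control does. Several matrix glycoprotein genes were lower in the negative-control library, whereas collagens and matrix proteases as lists were not. Fbn1 had 101.48 TPM against 345.29 TPM in untransfected cells, a log2 ratio of -1.80 (-1.83 to -1.77), with 382.61 TPM in the mimic library. Eln had 11.7, 38.74 and 53.31 TPM in that order, a ratio of -1.71 (-1.88 to -1.56). Tnc stood at -1.17 (-1.24 to -1.11), Dkk3, a secreted protein of the Dickkopf family, at -1.48 (-1.57 to -1.40), Exoc4 at -1.68 (-1.77 to -1.59), the TGF-beta family ligand Gdf11 at -1.59 (-1.79 to -1.39) and Npnt at -1.92 (-2.26 to -1.61). Matrix glycoproteins as a list were 2-fold lower for 4 of 36 genes and higher for none, with a median of -0.19 at percentile 0.0. The contractile list had a median of -0.27 and the Wnt and Hippo list of -0.39, both at percentile 0.0. For the TGF-beta response list the median was -0.15 at percentile 0.01. Collagens had a median of -0.04 at percentile 29.7, and matrix proteases and inhibitors had 0.00 at percentile 52.8. Markers of fibroblasts, at -0.19 and percentile 0.05, of pericytes and smooth muscle, at -0.41 and percentile 0.02, of cartilage and tendon, at -0.46 and percentile 0.29, and of osteoblasts, at -0.65 and percentile 0.1, were lower too. Macrophage markers had a median of 0.02 at percentile 85. Against untransfected cells the mimic library also had lower markers of pericytes and smooth muscle, at -0.37 and percentile 0.03. The same held for fibroblast markers, at -0.14 and percentile 0.34. Markers of cartilage and tendon, at -0.08 and percentile 30.3, and of osteoblasts, at 0.03 and percentile 64.6, did not stand apart there. Saa3 was lower after either oligonucleotide, at -2.51 (-2.93 to -2.15) with the negative control and -2.14 (-2.53 to -1.80) with the mimic.

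In this comparison 90 of 12532 genes were at least 2-fold lower and 37 at least 2-fold higher in the negative-control library, with 33 and 5 at 5 CPM or more. Apart from predicted and clone names, only 5 higher genes reached 5 TPM, among them C1qtnf6 at 1.01 (0.88 to 1.15) and Lmbr1l at 1.02 (0.62 to 1.44), while Zfp967 and Plac9a share reads with close copies. Of the genes measured in both transfection comparisons, 42 were lower in the negative control than in untransfected cells and higher with the mimic than with the negative control, of 75 and 90 such genes. Independent lists would share 0.542 genes. Simulated libraries without effects shared a mean of 1.3, because both comparisons use the negative-control library, and part of the excess may come from that library. The 107 genes higher with the mimic than with the negative control had a median ratio of mimic to untransfected cells of 0.38.

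A scan of all 7-base sequences in 3' UTRs put GCAGTAC lowest of 16193 in the ratio of the negative control to untransfected cells, at a z of -17.5. This sequence was singled out after its values were seen. The 788 measured genes that hold it had a median log2 ratio of -0.11, and the others 0.01. Random lists matched on expression and 3' UTR length had a median of 0.01. The 266 genes with GCAGTACA had a median of -0.15. It is present in the 3' UTRs of Fbn1, at 125301027 to 125301033 of chromosome 2, of Eln, at 134702946 to 134702952 of chromosome 5, and of Exoc4, at 33972324 to 33972330 and 33973490 to 33973496 of chromosome 6 (GRCm38). Npnt, Gdf11 and Dkk3 hold it too. Of the 2-fold lower genes with an annotated 3' UTR, 21 of 86 held it, 24.4% against 6.39% of all measured genes. The same genes had a median of 0.15 in the ratio of mimic to negative control and 0.03 in that of mimic to untransfected cells, where the percentile with length matching was 60.3.

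Genes that differed with the genotype were then followed into the mimic comparison, since a direct target would be higher in the knockout and lower with the mimic. With the negative control as the mimic's reference 3 genes, Entpd4, Rpl37rt and Perp, met both criteria, against 1.92 for independent lists of 745 and 32 genes among 12439. With untransfected cells as the reference 9 did, but both ratios then share the knockout library, and simulated libraries without a mimic effect gave a mean of 2.3 and at most 6 from counting error alone. Entpd4 had 54.28 counts in the wild-type, 163.1 in the knockout, 108.46 in the negative-control and 0 in the mimic library, at least 33.8-fold lower than with the negative control. Its near-identical neighbour Entpd4b had 1770.54 and 1750 counts with the negative control and the mimic, so the split of reads between the copies is uncertain. Perp, a p53-induced membrane protein, had a knockout to wild-type ratio of 1.48 (0.93 to 2.12), and 104 and 48 counts with the negative control and the mimic. The opposite pattern, lower in the knockout and higher with the mimic than with the negative control, held for 29 genes against 5.24 for independent lists, Eln, Tnc and Dkk3 among them. These 3 genes were lower with the negative control, and against untransfected cells the mimic ratios were 0.43 for Eln, 0.50 for Tnc and -0.21 for Dkk3. With that reference the pattern held for 12 genes, just above the highest number, 11, in 20 simulations without a mimic effect. Their mean was 5.35, and they hold counting error only. Against the negative control, overlaps in the same direction were also above those of independent lists, with 9 genes lower in both comparisons against 1.71 and 17 higher in both against 5.87. Across genes the log2 ratios of the 2 comparisons had a Pearson r of -0.0533 and a Spearman rho of -0.129. Without a filter on low counts r was 0.0039 and rho -0.0802, and at 5 CPM they were -0.11 and -0.168, and genes are not independent replicates.

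The authors' deposited table gives log2 ratios and false discovery rates from PoissonDis for 4 pairs of libraries. At a false discovery rate under 0.05 and at least 2-fold, the authors' deposited table lists 829 genes higher and 1032 lower in the knockout than in the wild-type library, and 98 higher and 80 lower with the mimic than with the negative control. For the negative control against untransfected cells the authors' deposited table lists 55 higher and 76 lower, and for the mimic against wild type 894 and 1061. Every log2 value in the authors' deposited table equalled the ratio of unscaled counts within 0.001, with 0 replaced by 0.01, so that library size is not removed. The scaling left out amounts to a log2 offset of 0.0966 for mimic against negative control and -0.165 for negative control against untransfected cells.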

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

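No paired analysis was possible because each group is a single library, and for the same reason no library could be left out. The 1.4-fold limit and the counts without genes holding GCAGTAC were chosen after seeing the data. With DESeq2 size factors all 11 main results kept their direction and moved by at most 1.5 times in counts or within their interval. Of 93 list medians 43 stood apart from random lists in the main setting. Standing apart was thus common here and does not by itself mark a list as exceptional. Across 6 alternatives none of 257 values of these 43 list medians changed sign, and 13 moved by more than the spread of random lists. None of 316 values of named genes changed sign, and 27 left their counting interval, 24 of them with TPM. Deposited TPM moved the median log2 ratio of all genes by -0.12 in the knockout to wild-type comparison and gave 433 genes higher there, 45 higher and 17 lower with the mimic than the negative control, 13 higher and 39 lower with the negative control than in untransfected cells, a correlation of -0.084 between the genotype and mimic ratios, and a median of -0.13 for genes with a miR-26a site in knockout against wild type. The logarithm of TPM + 1 compresses ratios of genes near 1 TPM. A filter at 5 CPM left fewer genes to test, with 556 lower in the knockout, 43 higher and 10 lower with the mimic, 5 higher and 33 lower with the negative control, and a correlation of -0.11. Without a filter more genes of few counts entered, with 82 lower with the mimic, 74 higher and 136 lower with the negative control and 5 genes higher in the knockout and lower with the mimic, while the Pearson correlation turned to 0.0039 and the rank correlation stayed negative, at -0.0802. A prior of 5 counts gave 24 lower with the mimic, 16 higher with the negative control and a correlation of -0.0709. A 4-fold limit gave 143 and 236 genes higher and lower in the knockout, 9 and 6 with the mimic, and 4 and 9 with the negative control. With the untransfected library as the mimic's reference 33 genes were higher, and 9 were higher in the knockout and lower with the mimic, a comparison in which both ratios share the knockout library, and the cause was not tested. At 1.4-fold 46 genes met the latter pattern, against 37.5 for independent lists. With total counts the median of genes with a miR-26a site was -0.0795 with the mimic and turned to 0.0121 in the knockout, as the scaling moved all genes by -0.04 and 0.04. For the mimic that median was -0.0839 with the 8-base site alone, -0.0299 with 7-base sites of the other register included, and 0.0125, the opposite sign, for passenger-strand sites. Random lists matched to the passenger-strand genes on expression and 3' UTR length had a median of 0.0234, which put these genes at percentile 5.42. The positive sign thus goes with 3' UTR length, and the cause of the other changes was not tested. Without genes holding GCAGTAC 77 genes were higher with the mimic and 69 lower with the negative control. Depth limits detection to about 0.151 to 0.170 CPM, the level of 3 counts.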

Other observations

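The imprinted, lysosome, osteoclast and class II antigen presentation lists, the tests of seed-type strength, all tests of the GCAGTAC pattern and those of fibroblast and macrophage shares were chosen only after the results were seen. Imprinted growth genes were lower in the knockout than in the wild-type library for 6 of 13 measured members and higher for none, with a median log2 ratio of -0.69 at percentile 0.03. Besides Mest, Dlk1, a regulator of adipocyte differentiation, had a ratio of -2.83 (-3.56 to -2.26), Plagl1, a zinc finger protein, of -2.09 (-2.41 to -1.80) and the growth factor Igf2 of -1.84 (-2.31 to -1.43). Mest had 29 counts in the knockout library and 71 and 73 after the negative control and the mimic, against 4044 in the wild-type library. Hox genes, which mark position along the body and limb, were lower for 7 of 28 members and higher for 1, with a median of -0.62 at percentile 0.04, and Hoxa6 had a ratio of -1.75 (-2.24 to -1.32). Immediate early genes were lower for 4 of 24, with a median of -0.28 at percentile 0.15 and Egr1 at -1.11 (-1.19 to -1.03). Lysosome genes had a median of 0.33 at percentile 99.8 without any reaching 2-fold, in the library where macrophage markers had a median of 1.06, and Ctsd, a lysosomal protease, had 11026.03 against 7118.12 TPM. Osteoclast genes had a median of -0.35 at percentile 2.53, and the 2 measured genes of class II antigen presentation had a median of 0.08.

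Single genes added to the pattern of the lists. Aif1, a cytoskeletal protein of macrophages, was lower with the mimic than with either reference, at -0.90 (-1.14 to -0.67) against the negative control and -0.85 (-1.10 to -0.62) against untransfected cells, while Cd14 was higher, at 0.41 (0.33 to 0.49) and 0.28 (0.20 to 0.36). Chondrocyte and tendon markers were higher with the mimic than with the negative control for 4 of 10 genes, with a median of 0.57 at percentile 100, but had a median of -0.08 at percentile 30.3 against untransfected cells. Hypoxia genes had a median of 0.18 at percentile 100 against the negative control and -0.01 at percentile 32 against untransfected cells.

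Genes with a miR-26a seed site were lower with the mimic, and the values argue against each of 3 technical sources as the only one. Matching random lists on 3' UTR length left the percentile at 0.0, so longer 3' UTRs do not account for it, and TACTTGA ranked 1 from the lowest among 420 rearrangements of its bases, which argues against base composition. With the untransfected library in place of the negative control the percentile was also 0.0, so the negative-control library is not the only source. The median was -0.0353 with the untransfected reference and -0.0443 with the negative control, so a contribution of the negative-control library stays open. Genes with the 8-base site lay at percentile 0.03 of lists drawn from all genes with a site, which is consistent with a seed-type effect of the mimic, as a hypothesis from 1 library. Whether the same genes are shifted between knockout and wild type stays open, since their percentile there was 95.4 with length matching and 0.01 without.

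Genes with GCAGTAC in the 3' UTR were lower in the negative-control library, and a candidate explanation is that a strand of the control siRNA acts on them through its seed. Random lists matched on 3' UTR length had a median of 0.0082, against -0.11 for these genes, and the other 603 rearrangements of the bases had a median z of 0.68 and a lowest z of -2.93, against -17.5, which argues against length and base composition. The untransfected library is not the source, since the mimic to negative-control ratio put the same genes at percentile 100 with length matching. Genes in which the sequence is followed by A lay at percentile 2.27 of lists drawn from all genes with it, close to the limit of 2.5, in the direction that a seed-type effect of the negative-control oligonucleotide predicts. The sequence of that oligonucleotide is not given in the sources used here, so the match stays untested, but it may be the reason that Fbn1, Eln and Exoc4 appear higher with the mimic than with this control.

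The knockout library differed from the wild-type library in 12.9% of measured genes. Within 10 Mb of Ctdspl and Ctdsp2, 18 of 215 measured genes differed 2-fold, 8.37%, at percentile 4.5 of 1000 random gene pairs. Differing genes were thus not concentrated in the flanking chromosome segments. This does not bear on strain differences elsewhere in the genome or on indirect effects of a flanking segment. A lower share of fibroblasts, with all other cell types kept in proportion, would put markers of the others higher alike. The upper quartile of the adipocyte markers was -0.27 and the lower quartile of the macrophage markers 0.89, which argues against that form only. Other cell types need not change together, and the test was set after these lists were seen, so a lower share of fibroblasts stays open. A larger share of macrophages over unchanged fibroblasts would lower fibroblast genes by 1 factor, but the lower quartile of the contractile genes, -0.43, lay above the upper quartile of the collagens, -0.72. A larger share or a changed state of macrophages, whose 20 markers occur in no other list used here and of which 19 were above 1 TPM in the wild-type library, may still contribute to the higher macrophage, lysosome, interferon and cell cycle genes. With 1 untransfected library per genotype, the genotype, the strain background and differences between cultures in outgrowth, cell makeup and growth state were not separated by these libraries. The sample title names C57BL6/J mice for the wild-type library, and the titles of the knockout libraries name no strain.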
